A study of Mus musculus with 2 samples.

How the data were processed

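Cells of the stromal vascular fraction, the non-adipocyte part of fat left after enzymatic digestion, came from epididymal white adipose tissue of male C57BL/6J mice. Per the labels, mice ate a standard diet for 16 weeks or a high-fat diet for 8 or 16 weeks, each suspension was stained with hashtag antibodies at 2.5 µg/ml, the suspensions were pooled, and 20000 cells entered a BD Rhapsody run with TAS-Seq library amplification. The series holds 2 libraries of that single pool, 1 for the transcriptome and 1 for the hashtags, so there was 1 pooled sample with no replicate. Hashtag antibodies bind surface proteins and carry a DNA barcode, which lets pooled suspensions be separated again after sequencing.

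The deposited transcriptome table holds whole-number read counts per gene and cell, and the deposited hashtag table holds whole-number counts per hashtag and cell barcode. Per the submitters' processing notes, the tools included cutadapt 2.10, Bowtie2 2.4.2 and R 3.6.3, and the genome build was GRCm38; the rules for cell calling, doublet calling and hashtag assignment are not given in the sources used here. The planned work assumed unique molecular identifiers. The deposited values run to 736281 per cell with a median of 31584.5 and were treated as reads, with no collapse to molecules recorded. Reads of 1 molecule are not independent, so every Poisson and binomial interval covers counting error only and is too narrow.

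The count table also lacks low values for part of the genes. Of the 18166 genes seen in over 100 cells, 389 have no value from 1 to 4, and the lowest value above 0 of Dcn is 19 reads. Among the 190 genes of the read-out lists, 114 have values down to 1 and 76 have a lowest value of 5 or more, up to 48 reads for Mmp12. A 0 of such a gene can stand for any count below that minimum, which lowers its level in cells that hold little of it and raises fold differences. An alternative therefore put 1 read less than the gene's lowest value in place of each 0, the largest amount that the gap can hide.

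The transcriptome table has 12040 cell columns and 29417 genes. The names of 12028 cells begin with the authors' hashtag call, 9 hashtags and a doublet call in all, and the other 12 columns carry no such name and were not used. The 12028 cells hold 617812192 reads, from 5169 per cell upward, with a median of 2500 genes per cell. Of the gene symbols, 28350 (96.4%) match GENCODE M21, an annotation of GRCm38, from which gene positions were taken. The hashtag table has 714687 barcodes, 15 hashtags and 53150260 counts.

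No label ties a hashtag to a diet. The hashtag populations were therefore kept as 9 unassigned samples, each given as its own value or as range and median, and the comparisons of standard with high-fat diet were not made. The planned rule for a hashtag population was a top tag with at least 2/3 of at least 10 tag counts. After the tag counts were seen, the authors' call replaced it, because fibroblast-like cells carry few tag counts and mostly miss that rule; the planned rule stands among the alternatives.

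Cells with at least 200 genes and at most 25% mitochondrial reads were kept, which removed 1253 cells. Of the rest, 254 hashtag doublets and 236 doublets called by Scrublet (expected rate 0.05) were removed, with 1 cell in both sets. Scrublet marked 0.394% of the hashtag doublets and 2.23% of the cells with 1 hashtag, so the calls hardly overlap. The median tag count was 31 in hashtag doublets and 707 in other cells. The 10286 remaining cells were scaled to 10000, log-transformed, and clustered by the Leiden method (resolution 1, seed 7) on 15 neighbours in 30 principal components of 2000 variable genes. Genes of the 18 read-out lists were left out of clustering. All of this ran in Python 3.11.15 with scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3; figures used matplotlib 3.10.9.

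Clusters were named from 24 marker lists of 170 genes fixed before the data were examined, 163 of them in the table, with at least 3 detected markers for a name. The scoring thresholds (55% of a class's markers, with refusal at 60% of a second class's markers, and below 60% also where 3 markers of a second class counted or no own marker led the cluster) were set after the clusters were seen, as were the rule that a subcluster carries another class's markers (80% of them) and the rule that a subcluster is high in a list (50% of its members 2-fold higher). These thresholds left 6 clusters with 12.9% of the cells without a name. Macrophage-like and fibroblast-like cells were each clustered again alone at resolution 1.

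Levels are summed reads of a class as CPM, with every class scaled to the same total. Ratios for counts of list members used CPM plus 1, with a 2-fold difference and at least 20 CPM in 1 of both classes as the limits; ratios printed for single genes have no pseudocount. A gene counted as detected in a cell at 6 reads. For shares of cells with a read and for cycling cells, each cell was thinned to 5000 reads, which no cell fell short of. Shares carry exact Clopper-Pearson 95% intervals and levels exact Poisson 95% intervals. For a share of 0, the limit given is 3 counts of the total. Cells are not replicates, so no test was run across them.

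The read-out lists, fixed before the data were examined, cover collagens, collagen processing, matrix degradation, matricellular proteins, TGF-beta and PDGF signalling, lipid-associated and resident macrophages, inflammatory genes, ligands and receptors between macrophages and fibroblasts, fibroblast progenitors, committed preadipocytes, Cd142-positive stromal regulators, MHC class II, interferon response, proliferation, dissociation response and regulatory T cells. All 190 genes were in the table, H2afz under its symbol H2az1. Named genes are, in each list, up to 4 members highest in macrophage-like and up to 4 highest in fibroblast-like cells at 20 CPM or more, and members detected in fewer than 1% of both classes as low. For subclusters they are up to 4 members per list with at least 50 reads and a ratio of at least 2 to the rest of the class. Between hashtag populations they are up to 10 members per class with the largest ratio of highest to lowest, among those with a lowest value above 0. Other genes were named after their values were seen, among them Trem2, Mmp3, Pdgfb, Csf1 and C3ar1.

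Clustering and naming were tested on 1450 simulated cells of 8 cleanly separated classes, all of which got the right name. For levels in fibroblast-like against macrophage-like cells, 100 genes changed 2-fold and 100 changed 4-fold all came out in the right direction, with median absolute log2 errors of 0.06 and 0.07. Thinning kept the means of 651 genes with a median relative error of 0.937%. Simulated binomial and Poisson intervals held the true value in 96.2% and 95.2% of 2000 draws each. Those draws came from the binomial and Poisson distributions themselves. No simulation included missing low values or several reads of 1 molecule. Alternatives covered the cell filter, clustering resolution, variable genes, doublet calls, hashtag rule, scaling, thinning and cycling rule; those for the mitochondrial limit, the planned hashtag rule, mixed subclusters, broad proliferation genes and the missing low values were added after the data were seen.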

Results

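Single-cell transcriptomes were measured in 1 pool of stromal vascular cells from epididymal fat of male mice on a standard diet for 16 weeks or a high-fat diet for 8 or 16 weeks. The series asks how macrophages and fibroblasts of fat communicate in obesity-induced fibrosis, the build-up of collagen-rich matrix. The pool was split by hashtag into 9 populations of 870 to 1691 cells, and 278 cells carried a doublet call. No source used here ties a hashtag to a diet, so diets were not compared. With 1 pooled library there is no replicate, and intervals cover counting error only. The 10286 cells kept had a median of 36709 reads and 2763.5 genes.

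Macrophage-like and fibroblast-like cells made up most of the pool. Macrophage-like cells, named by C1qa, C1qb, Adgre1 and Csf1r, were 32.9% of the 10286 cells (95% exact binomial interval 32.0 to 33.8). Fibroblast-like cells, named by Pdgfra, Dcn, Lum and Dpt, were 30.4% (29.6 to 31.3). Endothelial-like cells followed with 9.75% (9.18 to 10.3) and T cell-like cells with 5.92% (5.47 to 6.39). Mural-like cells, the contractile cells around vessels, were 2.91% (2.59 to 3.25), and mesothelial-like cells, which line the fat pad, were 2.88% (2.56 to 3.22). B cell-like cells were 1.27%, lymphatic endothelial-like cells 0.632% and mature dendritic cell-like cells 0.331%. The T cell-like class includes the 167 cells that were named natural killer cell-like at a finer clustering. It also holds a cluster of 123 cells led by Cd163l1, Trdc and Il17a, genes of gamma-delta T cells.

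A further 12.9% of the cells stayed without a name. Cluster 6 (5.72%) was led by the nuclear RNAs Malat1 and Neat1 and had a median of only 9766 reads. Its closest class was macrophage, with 4 of 10 markers counted: C1qc, Csf1r, Cd68 and Lyz2. Cluster 14 (2.88%) was led by Cd209a, Clec9a and Flt3, markers of both conventional dendritic cell types. Cluster 16 (2.28%) was led by Klrg1, Il1rl1, Il2ra and Gata3, genes known from type 2 innate lymphoid and regulatory T cells. Cluster 21 (1.15%) was led by the monocyte gene Plac8 and held Ccr2, cluster 22 (0.671%) by Sprr1a and Upk3a, and cluster 25 (0.243%) held macrophage and endothelial markers together. The macrophage-like share ranged from 28.4% to 39.9% and the T cell-like share from 1.05% to 8.21% over the other clustering and filter settings. Median reads were 70300 in macrophage-like, 45866 in fibroblast-like and 15455 in T cell-like cells.

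Collagen genes were higher in fibroblast-like than in macrophage-like cells. All 14 collagens of the list were at least 2-fold higher in fibroblast-like than in macrophage-like cells, and higher in each of the 9 hashtag populations. Col3a1 (GRCm38 chromosome 1, 45311538 to 45349706), a chain of fibrillar collagen III, reached 9652 CPM against 152 CPM, a 63.4-fold difference. Col1a1 (chromosome 11, 94936224 to 94953042), a chain of collagen I, reached 2221 CPM (95% Poisson interval 2214 to 2228) against 36.7 CPM (36.1 to 37.4). Col1a2 stood at 3823 CPM against 60.3 CPM and Col6a2 at 2081 CPM against 43.8 CPM.

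After thinning to the same depth, macrophage-like cells held collagen reads about as often as T cell-like cells, which should lack collagen. In cells thinned to 5000 reads, 10.4% of macrophage-like and 10.8% of T cell-like cells held a Col1a1 read, against 87.1% of fibroblast-like cells. The median depths before thinning were 70300 and 15455 reads in macrophage-like and T cell-like cells. Thinning shrinks a fixed amount of free RNA more in deeper cells, so similar shares do not decide where these reads come from. Without the subcluster of macrophage-like cells that carries fibroblast markers, the shares for Col3a1 were 33.2% of 3331 macrophage-like and 36.8% of 609 T cell-like cells. That subcluster, 1.65% of the macrophage-like cells, held 45.7% of their Col1a1 reads, at 804 CPM against 20.4 CPM in the others.

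Proteins that build and cross-link collagen followed the same direction, with 10 of 11 list members 2-fold higher in fibroblast-like cells and Plod1 within 2-fold. Serpinh1, the collagen chaperone HSP47, stood at 1949 CPM against 19.7 CPM. The lysyl oxidases Loxl1 and Loxl2 reached 700 CPM and 562 CPM against 8.38 CPM and 18.0 CPM, and Pcolce, an enhancer of procollagen cleavage, 501 CPM against 9.16 CPM. All 11 matricellular genes at 20 CPM or more were 2-fold higher in fibroblast-like cells, among them Sparc (9998 against 124 CPM), fibronectin Fn1 (6160 against 645 CPM), Fbn1 (3086 against 52.1 CPM) and Bgn (2698 against 51.3 CPM). The table lists no low values for some genes, and filling those gaps to the limit shrinks a difference. The differences then were still 18.8-fold for Serpinh1, 9.98-fold for Loxl1, 8.79-fold for Pcolce and 34.6-fold for Sparc.

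Matrix degradation was split between both classes. Mmp12 (chromosome 9, 7344381 to 7369499), the macrophage metalloelastase, stood at 2952 CPM in macrophage-like and 7.78 CPM in fibroblast-like cells, in the same direction in 9 of 9 hashtag populations. Its lowest recorded value is 48 reads, and with all gaps filled the difference was 3.68-fold. Mmp19 was 2.42-fold higher in macrophage-like cells, in 7 of 9 populations, and fell to 1.67-fold with gaps filled. The other 8 members at 20 CPM or more were higher in fibroblast-like cells, among them the gelatinase Mmp2 (746 CPM), the membrane protease Mmp14 (572 CPM) and the inhibitors Timp2 (4633 against 972 CPM) and Timp3 (545 CPM). With gaps filled, Mmp2, Mmp14 and Timp3 were 9.81-fold, 8.72-fold and 7.30-fold higher.

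In the TGF-beta and PDGF list, ligands were divided between both classes, 3 on each side, and most receptors were higher in fibroblast-like cells. Tgfb1, the profibrotic cytokine, was 7.51-fold higher in macrophage-like cells (159 against 21.2 CPM), and Pdgfb stood at 41.3 CPM against 1.35 CPM and Pdgfa at 22.1 CPM against 9.58 CPM. The ligands Tgfb2 (53.4 CPM), Tgfb3 (32.8 CPM) and Pdgfd (33.2 CPM) were higher in fibroblast-like cells. The receptor Tgfbr2 was 8.26-fold higher in fibroblast-like cells (570 CPM), and Tgfbr3 (324 CPM), the latent TGF-beta binding proteins Ltbp4 (866 CPM) and Ltbp1 (184 CPM) also lay there, Ltbp4 by 12.5-fold with gaps filled. In all, 9 members were 2-fold higher in fibroblast-like cells, 3 in macrophage-like cells, and Tgfbr1 was within 2-fold. Pdgfb was highest in endothelial-like cells (274 CPM) and Pdgfa in mural-like cells.

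**Figure D1:**
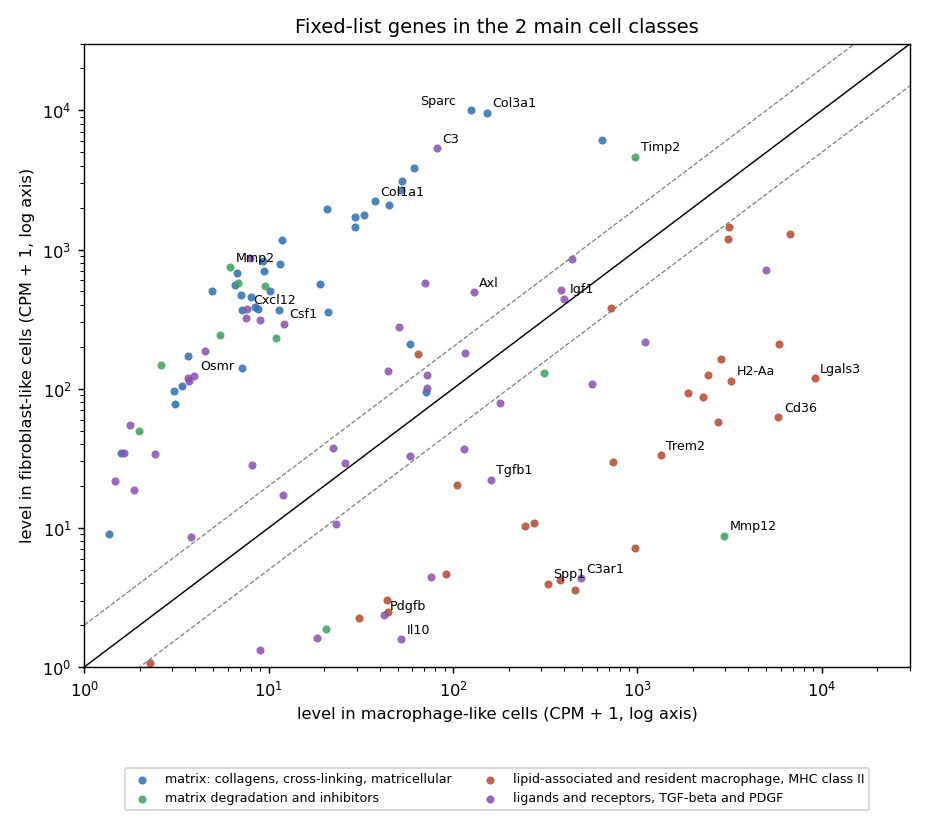
Each point is a gene of the fixed lists, with its level in macrophage-like cells (x) and in fibroblast-like cells (y) as CPM + 1 on log axes; the solid line marks equal levels and the dashed lines a 2-fold difference. Collagens such as Col3a1 (9652 against 152 CPM) sit above the lines, and Lgals3 (9141 CPM in macrophage-like cells) and Mmp12 below.

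Genes of the lipid-associated macrophage list were mostly higher in macrophage-like cells. Of the 13 genes of that list, 12 were 2-fold higher in macrophage-like cells and Cd9 was within 2-fold. Lgals3, a galectin of phagocytes, stood at 9141 CPM against 117 CPM, lipoprotein lipase Lpl at 6741 against 1286 CPM, and the fatty acid transporter Cd36 at 5819 against 61.1 CPM. Trem2 (chromosome 17, 48346401 to 48354147), a lipid receptor, was 41.4-fold higher (1336 against 32.3 CPM). Ctsl was 2.59-fold higher in sum but in only 6 of 9 hashtag populations, and fell within 2-fold when every cell counted equally. With gaps filled, Lgals3 was 19.6-fold and Cd36 13.3-fold higher. Cd36 was higher still in endothelial-like cells (8985 CPM).

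The MHC class II and proliferation lists also lay on the macrophage side. All 7 MHC class II genes, which present antigen, were 2-fold higher in macrophage-like cells, led by Cd74 (5840 against 210 CPM), H2-Aa (3222 against 113 CPM), H2-Ab1 (2723 against 56.4 CPM) and H2-Eb1 (2272 against 86.6 CPM). Of the resident macrophage list, 6 genes were higher in macrophage-like cells, led by Selenop (3118 against 1449 CPM) and Folr2 (459 against 2.58 CPM), whereas Gas6 was 2.77-fold higher in fibroblast-like cells in sum, but within 2-fold when every cell counted equally. All 11 proliferation genes at 20 CPM or more were 2-fold higher in macrophage-like cells, among them H2az1 (695 against 108 CPM), Tubb5 (518 against 219 CPM), Stmn1 (185 against 7.61 CPM) and Mki67 (107 CPM). With gaps filled, 6 proliferation genes kept a 2-fold difference. Ccl8, 1 of the 6 resident genes, then came to 1.28-fold and lost its call. H2-Ab1 then was 9.34-fold, Folr2 4.25-fold, H2az1 3.81-fold, Stmn1 1.93-fold and Mki67 1.58-fold higher.

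Ligands and receptors of macrophage and fibroblast crosstalk were divided between the classes. Csf1, the growth factor that keeps macrophages alive, was 26.4-fold higher in fibroblast-like cells (293 against 11.1 CPM). Complement C3 stood at 5368 CPM in fibroblast-like and 80.9 CPM in macrophage-like cells, while its peptide receptor C3ar1 stood at 493 CPM in macrophage-like and 3.35 CPM in fibroblast-like cells. The chemokine Cxcl12 was at 372 CPM against 6.67 CPM and its receptor Cxcr4 at 3.46 CPM against 74.8 CPM, in the same order of classes. Among the named classes, C3 was highest in mesothelial-like cells. Cxcl12 was higher still in endothelial-like cells, and Cxcr4 in T cell-like cells. Fibroblast-like cells also had more Il34, Axl (492 against 129 CPM), Egfr (310 CPM), Osmr, Il1r1, Il6st and Igf1r. Macrophage-like cells had more Apoe (4998 against 715 CPM), Grn (1094 against 214 CPM), Mif (179 against 78.3 CPM), Il10, Cd44 (568 against 108 CPM) and Tnfrsf1b. Igf1 was close in both, at 401 CPM in macrophage-like and 442 CPM in fibroblast-like cells, as were Hbegf, Vegfa, Lrp1, Tnfrsf1a, Itgav, Itgb1 and Itgb5, all within 2-fold. Osm and Areg stayed below 20 CPM in both. With gaps filled, the differences were 7.12-fold for Cxcl12, 4.43-fold for C3ar1, 3.01-fold for Cd44 and 1.18-fold for Il10.

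Inflammatory genes were split as well, with 5 members 2-fold higher in fibroblast-like and 6 in macrophage-like cells. Fibroblast-like cells held more Il6 (276 against 5.21 CPM), Ccl7 (610 against 77.4 CPM) and Ccl2 (564 against 243 CPM), a monocyte attractant, together with Cxcl10 and Ptgs2; with gaps filled Il6 was 5.82-fold and Ccl7 5.08-fold higher. Macrophage-like cells held more Cxcl2 (2234 against 77.9 CPM), a neutrophil attractant, and Tnf (84.2 against 3.63 CPM), together with Il1b, Ccl3, Ccl4 and Clec4e. With gaps filled Ccl4 came to 1.29-fold and Il1b lost its difference, and Il1b and Clec4e lost the 2-fold call at Leiden 0.5. Cxcl1 was within 2-fold, at 524 CPM in macrophage-like and 602 CPM in fibroblast-like cells. The dissociation response, a set of immediate early genes that enzymatic digestion can switch on, was higher in fibroblast-like cells for 9 of 11 genes. Examples are Fos (6064 against 2395 CPM), Egr1 (2777 against 559 CPM) and Jun (2554 against 677 CPM); Atf3 (1631 against 1085 CPM) and Hspa1a were within 2-fold.

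Stromal progenitor genes marked the fibroblast-like cells. Of the progenitor list, 5 genes were 2-fold higher there, with Cd55 at 1084 CPM, Pi16 at 787 CPM and Sema3c at 388 CPM, and Anxa3 (447 against 250 CPM) was within 2-fold. All 4 of the Cd142-positive regulator genes at 20 CPM or more were higher there too: F3 (157 CPM), which encodes Cd142, Fmo2 (256 CPM), Gdf10 (164 CPM) and Clec11a (45.3 CPM). With gaps filled, the differences were 13.1-fold for Cd55, 7.57-fold for Sema3c and 5.02-fold for Fmo2. The committed preadipocyte list did not follow: Fabp4, Cebpa and Pparg, genes of adipocyte differentiation that other cells also use, were higher in macrophage-like cells (416, 84.0 and 44.4 CPM against 169, 16.2 and 7.17 CPM). Fabp4 was highest in endothelial-like cells, at 21030 CPM. Lifr was 2.29-fold higher in fibroblast-like cells and Icam1 within 2-fold. Interferon response genes were low: 4 of 10 reached 20 CPM, of which Irf7 (38.0 CPM), Ifit2 (34.0 CPM) and Ifit1 (30.7 CPM) were higher in fibroblast-like cells and Oasl2 was within 2-fold. No regulatory T cell gene reached 20 CPM in either class; Ctla4 stood at 168 CPM in T cell-like cells. Timd4, Nos2, Dlk1, Ifi44, Foxp3, Ctla4 and Klrg1 were detected in fewer than 1% of both classes.

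Over all lists, 90 genes were 2-fold higher in fibroblast-like and 58 in macrophage-like cells. With the mean of per-cell CPM the counts were 86 and 53, with thinned cells 86 and 55, and with gaps filled 90 and 48. Ccl2, Gas6, Il34, Irf7, Lifr, Mif, Ctsl, Ccnb1 and Nusap1 lost the 2-fold call both with the mean of per-cell CPM and with thinned cells, and Pdgfa with the mean only. No gene passed to 2-fold in the opposite direction under any of these settings. With gaps filled Il1b and Cdk1 came to 0.970-fold and 0.982-fold, so their direction rests on the missing low values being near 0.

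Macrophage-like cells fell into 11 subclusters. Subcluster 9 (5.34%), led by Lyve1 and Cd209f, carried resident macrophage genes: Cbr2 at 1371 CPM against 19.1 CPM in the other macrophage-like cells, F13a1 at 1576 against 63.5 CPM, Cd163 at 555 against 20.4 CPM and Timd4 at 40.4 against 0.563 CPM. It also held more of the chemokines Ccl7 (827 against 64.0 CPM) and Ccl2 (766 against 233 CPM). Dissociation genes moved with them, 10 of 11 being 2-fold higher, such as Hspa1a (443 against 93.3 CPM), and its median was only 23138 reads. Of the regulatory T cell list, low in the class as a whole, 4 of 5 genes were 2-fold higher there as well. Subcluster 3 (14.1%), led by Plbd1, Retnla and Ccr2, was high in MHC class II with H2-Ab1 at 8008 against 2237 CPM, in Il1b (322 against 15.2 CPM) and in Fn1 (4062 against 331 CPM). Subcluster 1 (16.1%), led by Ms4a6b, had more Selenop (10011 against 2199 CPM), Apoe (13395 against 3878 CPM) and H2-Aa (6153 against 2831 CPM), and its dissociation genes, such as Egr1 (1356 against 453 CPM), were higher too.

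The other macrophage-like subclusters are described by single genes, apart from those high in proliferation and subcluster 10. Subcluster 6 (8.59%), led by Serpinb9b, Gclm, Srxn1 and Prdx1, the last 3 being genes of the antioxidant response, held Mmp12 at 10538 CPM against 1758 CPM, though of the matrix degradation list 2 genes were 2-fold higher there and 3 lower. Subcluster 7 (7.74%), led by Mfge8, Acp5 and Ctsk, held Gpnmb at 5877 against 2485 CPM and Ctsl at 5733 against 2774 CPM. Subcluster 2 (15.8%), led by F7 and Il1rn, held Mmp19 at 667 against 241 CPM. Subcluster 4 (11.0%), led by Cpe and Hmga2, held Folr2 at 1111 against 341 CPM and Pdgfb at 77.6 against 34.7 CPM. Subcluster 5 (9.33%) had 12 of 12 proliferation genes 2-fold higher, with Mki67 at 595 against 26.0 CPM. Subcluster 10 (2.69%), led by Cxcl9 and Gbp2, held interferon-induced genes, with Cxcl10 at 440 against 8.34 CPM, Ifit2 at 158 against 3.73 CPM and Ccl8 at 1722 against 68.1 CPM. In it, 10 of 10 interferon response genes and 7 of 7 MHC class II genes were 2-fold higher. Subcluster 8 (7.65%) had a median of 34195 reads and was led by Gm23935 and Gm24270, and subcluster 11 (1.65%) carried fibroblast markers and had 10 of 12 proliferation genes 2-fold higher.

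Fibroblast-like cells fell into 12 subclusters. Subcluster 1 (16.6%), led by the complement gene C4b and by Mdk, was high in no list as a whole. Of the matrix degradation list, 5 of 11 genes were 2-fold higher and 2 lower, and of the collagens 3 of 14 were higher and 1 lower. Single genes were Col1a1 at 3800 CPM against 1848 CPM in the other fibroblast-like cells, Mmp2 at 1655 against 531 CPM, Mmp3 at 428 CPM, 5.36-fold higher, and Timp1 at 549 against 156 CPM. The same subcluster held more Cxcl12 (1075 against 206 CPM), Apoe (2533 against 286 CPM) and Lpl (2979 against 886 CPM). In each of the 9 hashtag populations, its levels of Col1a1, Cxcl12 and Mmp3 were above those of the other fibroblast-like cells of all populations together. Subcluster 5 (10.4%), led by Duoxa1 and Smpd3, was high in progenitor genes, with Cd55 at 2600 against 820 CPM, Wnt2 at 62.4 against 10.1 CPM and Dpp4 at 521 against 169 CPM, and also in Fn1 (13790 against 4829 CPM) and Fbn1 (7500 against 2317 CPM). Of the 11 dissociation genes, 10 were 2-fold lower in it, as were 8 inflammatory genes. Subcluster 2 (471 cells), led by Ptx3 and Has1, was high in Pi16 (1820 against 578 CPM) and in inflammatory genes such as Cxcl10 (362 against 47.9 CPM) and Ccl2 (1521 against 371 CPM).

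Among the other fibroblast-like subclusters, subcluster 7 (6.93%), led by Chrdl1 and Ccn5, carried the Cd142-positive regulator genes Fmo2 (1508 against 181 CPM), Clec11a (258 against 32.6 CPM) and Gdf10 (547 against 141 CPM) and the matrix gene Fmod (278 against 19.1 CPM). Subcluster 9 (5.78%), led by Col8a1 and Cilp, held elastin Eln at 1380 against 271 CPM and Ccn2 at 508 against 138 CPM. Subcluster 4 (375 cells), led by Hmcn2 and Abca8a, held the basement membrane gene Col4a1 at 3194 against 1205 CPM, and subcluster 6 (9.58%), led by Trf and Apod, held Igf1 at 1180 against 372 CPM, Lifr at 130 against 36.4 CPM and Cebpa at 43.0 against 13.7 CPM. Subcluster 8 (6.48%) was led by the stress genes Nr4a3, Maff and Cdkn1a and held Il6 at 778 against 246 CPM and Fosb at 3534 against 1494 CPM. Subcluster 3 (469 cells) had a median of only 14221 reads and was led by mitochondrial RNAs. Subcluster 10 (1.57%) carried macrophage markers, and subclusters 11 and 12 had 14 and 5 cells.

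Cycling cells were common among macrophage-like cells and rare among fibroblast-like cells. In cells thinned to 5000 reads, 23.8% of macrophage-like cells (95% interval 22.4 to 25.3) and 1.34% of fibroblast-like cells (0.968 to 1.81) held reads of at least 3 of the 12 proliferation genes. The share was 6.24% in T cell-like cells, 2.89% in endothelial-like cells and 16.9% in the dendritic cluster 14. With at least 5 genes the shares were 10.3% and 0.319%, without the broadly expressed Stmn1, Tubb5 and H2az1 they were 9.45% and 0.256%, and in unthinned cells 49.4% and 11.5%. The 9 hashtag populations ranged from 15.1% to 31.6% in macrophage-like cells, with each above the 0.596% to 3.45% found in fibroblast-like cells. Without Stmn1, Tubb5 and H2az1 the macrophage-like range was 4.30% to 17.2%, with another population highest. Low values are missing for 6 of the 12 genes, Mki67, Top2a, Cdk1, Stmn1, Tubb5 and H2az1, which deeper cells pass more often, and thinning does not restore them.

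The makeup of the 9 hashtag populations varied widely. Macrophage-like cells were 6.69% to 48.4% of a population's cells with a median of 37.9%, and fibroblast-like cells 14.6% to 52.6% with a median of 26.2%. Mesothelial-like cells ranged from 0.840% to 7.85%, T cell-like cells from 2.93% to 10.6%, endothelial-like cells from 6.37% to 13.2%, and cluster 16 from 0 of 1191 cells, which by 3 counts of the total allows a share of up to 0.252%, to 4.94%. These values rest on the authors' hashtag calls, and hashtags were weak on fibroblast-like cells. Their median was 45 tag counts with 53.8% from the top tag, against 2290 counts and 98.0% in macrophage-like cells, and the call equalled the top tag in 83.1% against 98.7% of the cells. At a top tag of 2/3 or more, 31.9% of fibroblast-like and 96.5% of macrophage-like cells had a call. The fibroblast-like share then ran from 7.45% to 22.5% and the macrophage-like share from 11.9% to 56.3%.

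**Figure D2:**
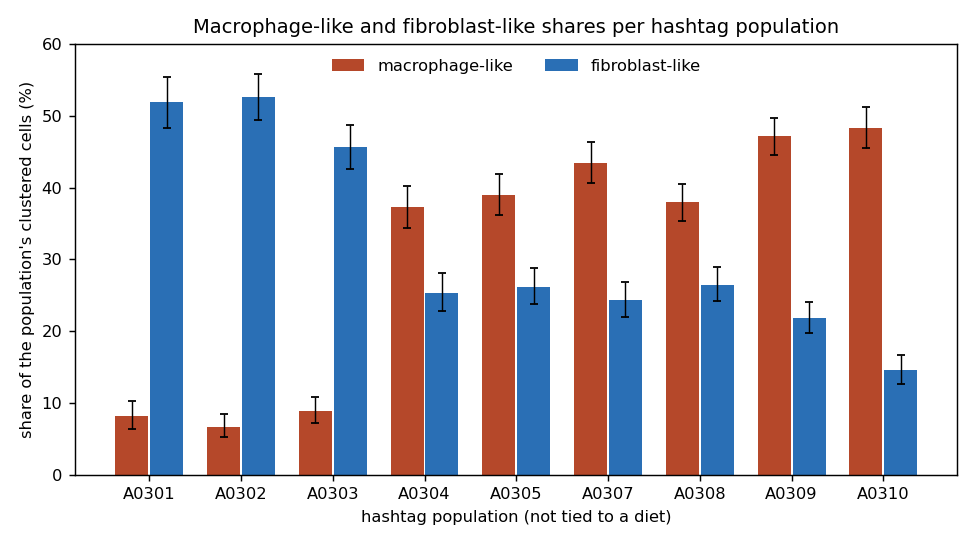
Bars give the share of each hashtag population's clustered cells (%, y) that were macrophage-like or fibroblast-like, for the 9 hashtags (x), with exact 95% binomial intervals for counting error. Macrophage-like shares run from 6.69% to 48.4% and fibroblast-like shares from 14.6% to 52.6%.

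Within fibroblast-like cells, the 10 list genes with the largest ratio between hashtag populations, among those above 0 in every population, came from several lists. Mmp12 (0 to 38.5 CPM) and Spp1 (0 to 22.8 CPM) have no such ratio. The protease Mmp3 ranged from 46.5 to 492 CPM with a median of 102 CPM, and its inhibitor Timp1 from 96.3 to 765 CPM with a median of 185 CPM. Both were higher in fibroblast-like subcluster 1 (5.36-fold and 3.52-fold), whose share ran from 6.30% to 42.6%, and the ranges were not separated from the mix of subclusters. The small proteoglycan Fmod ranged from 8.57 to 91.4 CPM, Ltbp2 from 7.36 to 48.3 CPM, Cxcl10 from 26.3 to 219 CPM, Bmp7 from 6.67 to 44.9 CPM and Ccl8 from 4.78 to 32.9 CPM. The proliferation gene Stmn1 ranged from 1.87 to 20.9 CPM. H2-Ab1 ranged from 6.73 to 138 CPM and Cd36 from 9.46 to 178 CPM; both were higher in the subcluster with macrophage markers, Cd36 at 900 against 37.7 CPM.

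Within macrophage-like cells, where Lox, Ccl5, Ptgs2 and Cd55 were 0 in at least 1 population and have no ratio, Ccl8, a chemokine of resident macrophages, ranged from 2.35 to 442 CPM, Cxcl10 from 1.53 to 115 CPM, Il6 from 1.05 to 50.2 CPM and the growth factor Areg from 0.456 to 27.8 CPM. Postn (0.959 to 188 CPM), Sema3c (0.746 to 70.0 CPM), Col5a2 (1.12 to 61.0 CPM), Col14a1 (1.39 to 73.7 CPM), Col5a1 (0.987 to 50.7 CPM) and Inhba (0.261 to 27.0 CPM) also varied. Nor were these ranges separated from the mix of subclusters: Ccl8 stood at 1722 against 68.1 CPM in subcluster 10, Il6 at 30.5 against 2.89 CPM in subcluster 3, and in the subcluster with fibroblast markers Il6 stood at 83.2 against 3.55 CPM and Cxcl10 at 183 CPM, 13.02 times the level elsewhere. Of the others, Col5a2 stood at 437 CPM in the macrophage-like subcluster with fibroblast markers against 1.81 CPM elsewhere and Col14a1 at 327 against 1.52 CPM. That subcluster held between 0.858% and 6.25% of a population's macrophage-like cells, and 64 such cells were the fewest in any population.

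**Figure D3:**
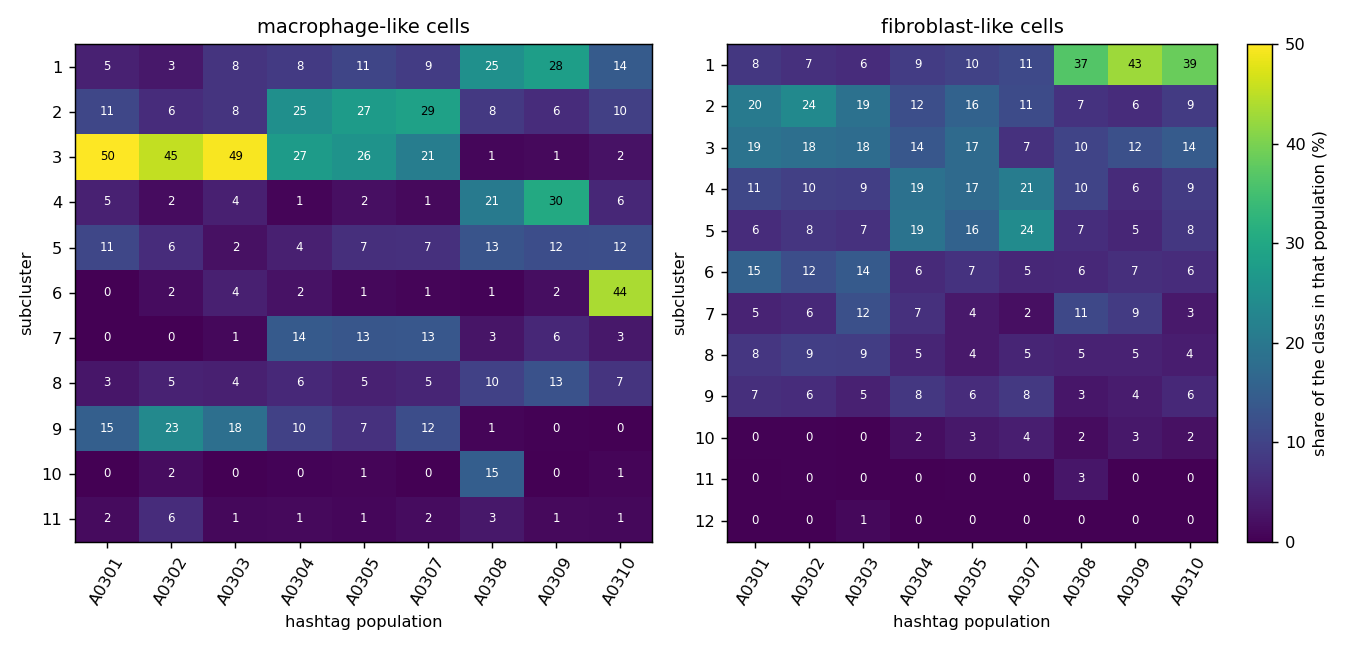
Heat maps give the share of a population's macrophage-like (left) or fibroblast-like (right) cells in each subcluster (y) for the 9 hashtags (x); numbers and colour are percent. Macrophage-like subcluster 3 runs from 0.945% to 50.0% and fibroblast-like subcluster 1 from 6.30% to 42.6%.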

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

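Of the tests below, the one of free RNA for collagen reads and the one of mesothelial cells for cluster 22 were written after their results were seen. The test of wrong hashtag calls for cluster 22 was given a further condition beyond the rule set beforehand. Among 44 sets of 9 hashtag populations, 6 had 1 population far from the other 8, measured as its gap to the next value over the whole range. For independent, normally distributed values chance does so in about 1 in 20 sets. Most sets here are shares of the same cells, which depend on each other, and the subclusters were formed on those cells. That rate therefore need not hold for these sets. The design ties no population to a diet, so no explanation by diet was tested for any of these results.

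Collagen reads in macrophage-like cells were weighed because they bear on whether macrophages themselves make matrix. The test of free RNA from fibroblast-like cells cannot decide, because thinning shrinks a fixed amount of free RNA more in deeper cells. Median depths were 70300 reads in macrophage-like and 15455 reads in T cell-like cells. Outside the subcluster with fibroblast markers, the median log2 ratio of macrophage-like to T cell-like cells with a read was 0.11 over 14 collagens. It lay inside the range predicted for free RNA. It was -0.15 for the 7 collagens with values down to 1 read and 0.21 for the other 7, with Col14a1 highest at 2.87; a first version over all macrophage-like cells gave 0.26. Doublets gathered in the subcluster with fibroblast markers are not the whole cause for Col1a1: that subcluster, 1.65% of the cells, held 45.7% of its reads. The binomial interval of 44.7% to 46.6% lies below the 50% set beforehand, but reads of 1 cell are not independent. The 95% range over cells drawn again with replacement, chosen after the value was seen, runs from 23.8% to 61.6%. Whether the subcluster holds 50% or more thus stays open, and doublets outside it were not tested.

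Macrophage-like subcluster 6, rich in Mmp12 and Gclm, held 43.6% of the macrophage-like cells of population A0310, against 4.30% in the next population. Wrong hashtag calls are excluded, since the top tag held a median of 98.7% of the tag counts of its 251 cells there. Among macrophage-like cells of 60000 reads or more, the share in A0310 was still 3.72 times the highest other share (51.3% against 13.8% in A0303, 95% intervals for counting error 46.4 to 56.2 and 3.89 to 31.7). Cells below 60000 reads therefore do not account for the difference. Depth above that floor was not matched between populations, so depth as a whole is not excluded. Doublets with another cell type are excluded, since the highest share of another class's markers raised in subcluster 6 was 0% over 22 classes. Doublets between macrophage-like cells would raise no such marker and were not tested. Subcluster 6 had the highest median reads of the macrophage-like subclusters, 130987. A real difference of that population remains a hypothesis, and a difference in how its suspension was handled was not tested.

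Cluster 22, led by Sprr1a and Upk3a, held 3.74% of population A0303, against 0.732% in the next population. Wrong hashtag calls stay open. The median top-tag share of its A0303 cells was -25.5 points from that of the other A0303 cells, which met the limit set beforehand for wrong calls. But cell types bind hashtags differently, and fibroblast-like A0303 cells were at 45.2% against 47.1% here. That comparison with fibroblast-like cells was not part of the rule set beforehand. At a top tag of 2/3 or more A0303 was still highest, at 1.65% against 0.833%; at 90% or more it held 0 of 353 cells, with only 8 cells of cluster 22 left in all populations. Mesothelial cells in another state stay open too: 55.6% of the mesothelial markers (5 of 9, 95% interval 21.2 to 86.3, among them Msln and Wt1) lay 4-fold or more below their mesothelial-like level, the other 4 (Upk1b, Krt19, Krt18 and Krt8) lay above it, and a first version, a median log2 ratio of -2.81 with a spread of 4.17, also decided nothing. Urothelial cells carried over from another tissue fit the prediction, since 100% of 9 urothelial genes were 4-fold above every named class, with Krt5 at 1224 CPM and Upk2 at 849 CPM. That list was not among the marker lists fixed beforehand. Apart from mesothelial-like cells no named class is an epithelial cell type, so the test cannot tell urothelium from other epithelia. The epididymal epithelium markers Epcam (264 CPM) and Cdh1 (421 CPM) also counted in cluster 22, and that tissue was not tested.

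Macrophage-like subcluster 10, with Cxcl9 and Gbp2, held 14.9% of the macrophage-like cells of population A0308, against 1.56% in the next. Fibroblast-like subcluster 11, with Cxcl9 and Iigp1, also stood apart in A0308, at 2.98% against 0.344%. Macrophage-like subcluster 11, with fibroblast markers, held 6.25% (4 of 64 cells) in A0302, against 3.21% in the next. Fibroblast-like subcluster 12 held 1.05% in A0303 and 0% elsewhere; its 5 cells are led by adipocyte genes such as Adipoq and Cfd, with 14 of 14 collagens 2-fold lower than in the rest of the class, and cells found in 1 population only stand apart by construction. Hashtags that name no cell had counts in the hashtag table, data outside the main measurement: 27340 for A0306, 3387 for A0312, 850 for A0311, 90 for A0313 and 59 for A0315.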

How the results depend on the processing

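The alternatives without a mitochondrial filter, with the top tag at 2/3, without Stmn1, Tubb5 and H2az1, without subclusters of mixed markers and with gaps filled were chosen only after the data were seen. Of 592 alternative values, 507 stayed within their interval or within 1.5 times a count and 85 moved. A reversal of direction was not scored. Of the 196 that concern class shares, hashtag populations, subclusters, cycling cells and list totals, 79 moved; of the 396 counts for single lists, 6 did. The totals of list genes 2-fold higher in fibroblast-like and in macrophage-like cells held under all alternatives, as did the shares of B cell-like, lymphatic endothelial-like, mature dendritic cell-like and mesothelial-like cells and the share of fibroblast-like cells in Cd142-high subclusters. For the clustering values that moved, the cause was not tested; shares move with the tag and cycling rules by construction.

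For comparison, and without subclusters of mixed markers, subclusters high in resident genes held 21.5% of macrophage-like cells, those high in MHC class II 32.9%, in interferon genes 2.69% and in proliferation 9.33%; progenitor-high subclusters held 25.5% of fibroblast-like cells. With the stricter cell filter, pool shares were 39.9% macrophage-like, 32.2% fibroblast-like, 9.03% endothelial-like, 4.03% T cell-like and 2.57% mural-like. The populations' macrophage-like shares then ran from 10.1% to 60.7%, and subclusters high in resident, MHC class II, proliferation and progenitor genes held 14.5%, 17.3%, 7.09% and 27.5%. Leiden 0.5 gave 28.4% macrophage-like, 8.21% T cell-like, a lowest macrophage-like share of 3.87%, and 5.14% resident, 16.4% MHC class II and 27.4% progenitor. Leiden 2.0 gave 35.6% macrophage-like, 4.30% T cell-like, a highest macrophage-like share of 54.2%, and 18.2% resident, 19.5% MHC class II, 7.68% proliferation and 23.4% progenitor. With 4000 variable genes, 36.2% were macrophage-like, the highest population had 55.2%, and subclusters held 5.13% resident, 3.38% interferon and 23.4% progenitor. With read-out genes kept in clustering, 39.8% were macrophage-like (populations 9.83% to 58.7%) and 4.37% T cell-like, with 27.9% MHC class II and 7.47% proliferation. With doublet calls kept, 38.5% were macrophage-like (populations 10.1% to 57.8%) and 4.32% T cell-like, with 19.1% resident, 25.9% MHC class II, 3.95% interferon and 6.62% proliferation. With no mitochondrial filter, 27.2% were fibroblast-like, 9.05% endothelial-like and 1.05% T cell-like, the highest macrophage-like share was 45.5% and the lowest fibroblast-like share 11.8%, with 27.5% resident, 1.94% interferon, 7.43% proliferation and 23.6% progenitor.

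Under the authors' calls 97.7% of cells had 1 hashtag, and populations held 7.23% to 14.1% of all cells. With the top tag at 50% or more, 83.8% of cells had 1 hashtag, populations held 4.93% to 12.8% of all cells, macrophage-like shares ran from 9.49% to 52.5% and fibroblast-like shares from 9.84% to 34.98%. At 2/3 these were 73.3%, 3.85% to 11.7%, 11.9% to 56.3% and 7.45% to 22.5%. At 90% they were 57.4%, 2.84% to 9.31%, 14.5% to 63.1% and 2.34% to 9.70%. Cycling macrophage-like and fibroblast-like cells were 49.4% and 11.5% unthinned, 10.3% and 0.319% with at least 5 genes of the list, and 9.45% and 0.256% without Stmn1, Tubb5 and H2az1.

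Another 6 moved values were counts of single lists, such as 2-fold higher macrophage-like proliferation genes, 11 as reported and 6 with gaps filled. Depth limits the comparison of detection between classes, from a median of 70300 reads in macrophage-like to 14779 in B cell-like cells. The settings planned for the diet contrasts were not run: DESeq2, no filter on low counts, a replicate block, leaving out each hashtag population, and the tag rules. No paired analysis was possible because the hashtags carry no replicate numbers and are not tied to diets.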

Other observations

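Nothing in this part was tested, and all of it was chosen after the results were seen. Vessel-associated cells carried matrix and growth factor genes of their own. Of the named classes, mural-like cells were highest in the PDGF receptor Pdgfrb, at 635 CPM against 118 CPM in fibroblast-like cells, in the metalloprotease inhibitor Timp3 (5550 CPM) and in the basement membrane collagen Col4a1 (1849 CPM). Endothelial-like cells, which take up fatty acids in fat, held Fabp4 at 21030 CPM, Cd36 at 8985 CPM, the PDGF ligand Pdgfb at 274 CPM and the chemokine Cxcl12 at 682 CPM. Lymphatic endothelial-like cells held Tgfbr2 at 599 CPM and Timp3 at 3801 CPM.

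Mesothelial-like cells, the lining of the fat pad, were the highest of the named classes for complement C3 (7328 CPM), for the Axl ligand Gas6 (1378 CPM) and for the proteoglycan Fmod (1411 CPM against 33.7 CPM in fibroblast-like cells). T cell-like cells held the chemokine Ccl5 at 2922 CPM, the growth factor Areg at 42.8 CPM and Cxcr4, the Cxcl12 receptor, at 150.2 CPM. Among named classes, Cd74 was highest in mature dendritic cell-like cells, at 18809 CPM, followed by B cell-like cells with 9632 CPM.

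The 9 hashtag populations, which the labels tie to no diet, had values that fall into separate clusters. In the order A0301, A0302, A0303, A0304, A0305, A0307, A0308, A0309 and A0310, macrophage-like cells were 8.15%, 6.69%, 8.92%, 37.3%, 39.0%, 43.5%, 37.9%, 47.1% and 48.4% of the cells. Fibroblast-like cells were 51.9%, 52.6%, 45.6%, 25.4%, 26.2%, 24.4%, 26.5%, 21.8% and 14.6%. By both, the first 3 populations stand apart from the other 6. The fibroblast-like values rest on weak hashtags: the call equalled the top tag in 67.6% of fibroblast-like cells in A0303 and 67.8% in A0308, and the highest fibroblast-like share fell to 22.5% at a top tag of 2/3 or more and to 9.70% at 90% or more. Mesothelial-like cells were 4.94%, 7.85%, 5.46%, 3.44%, 1.09%, 3.18%, 0.861%, 0.980% and 0.840%, and cluster 16, with Klrg1 and Il1rl1, was 4.94%, 4.18%, 2.68%, 3.16%, 3.52%, 2.93%, 0.789%, 0.350% and 0%.

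Within the classes, 7 of 23 subclusters are given here, chosen because they set at least 1 of these sets of populations apart: A0301 to A0303; A0304, A0305 and A0307; and A0308 to A0310. Macrophage-like subcluster 2 and fibroblast-like subcluster 5 set only the middle set apart. Others follow none of these sets, such as macrophage-like subcluster 6 (43.6% in A0310 and at most 4.30% elsewhere), subcluster 10 (14.9% in A0308 and at most 1.56% elsewhere) and subcluster 4 (30.3% in A0309, 20.6% in A0308 and 5.56% in A0310). Macrophage-like subcluster 3, with Ccr2 and Retnla, held 50.0%, 45.3%, 49.5%, 27.4%, 25.8%, 21.2%, 0.945%, 1.34% and 2.43% of the macrophage-like cells. Subcluster 9, with Lyve1 and Cd209f, held 15.2%, 23.4%, 18.3%, 9.73%, 7.08%, 11.8%, 0.756%, 0.297% and 0%. Subcluster 2, with F7 and Il1rn, held 10.6%, 6.25%, 7.53%, 24.9%, 27.5%, 28.5%, 8.32%, 6.39% and 9.55%, and subcluster 7, with Mfge8 and Acp5, 0%, 0%, 1.08%, 14.2%, 13.3%, 13.5%, 2.84%, 5.65% and 3.30%. Fibroblast-like subcluster 1, with C4b and Mdk, held 8.10%, 6.96%, 6.30%, 8.79%, 9.90%, 11.0%, 36.6%, 42.6% and 38.5% of the fibroblast-like cells. Fibroblast-like subcluster 5, with Duoxa1 and Smpd3, held 6.43%, 7.75%, 7.14%, 19.0%, 15.7%, 24.1%, 6.504%, 5.45% and 8.05%, and subcluster 2, with Ptx3 and Has1, 20.5%, 23.7%, 18.7%, 12.1%, 15.7%, 11.3%, 7.32%, 6.41% and 8.62%.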
